A study of Caenorhabditis elegans with 4 samples.

How the data were processed

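Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where LIN-35 sits on the genome of Caenorhabditis elegans. LIN-35 is the worm homologue of the retinoblastoma protein Rb. It was expressed as a GFP and FLAG fusion from the promoter of mex-5, a promoter active in the germline, in a strain that also carries an unc-119 rescue gene. Hermaphrodites were raised at 20 degrees Celsius to the young adult stage and fixed with formaldehyde at 2%. Per the labels' protocols, whole worms were lysed and sonicated, part of the lysate was kept as input, and the rest was precipitated with an antibody against GFP. The labels list 2 precipitated samples and 2 inputs, numbered as replicates 1 and 2. Nothing in the labels says whether the replicates came from separate cultures.

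There were 3 peak lists: 1 for each precipitated sample and 1 combined list. No processed file of an input was analysed here. Per the file headers, coordinates are on the WormBase WS220 build and peaks were called by the authors with PeakSeq, a program that compares a precipitated sample with a control. Comment lines in the files record a liftover step and name 2 peaks per list whose internal structure it changed; the build before it is not given. The aligner, the PeakSeq version, the control and the rule by which the combined list was made are not given in the sources used here. Each peak has a start, an end and a q-value, as deposited by the authors, and no summit, height or fold. The q-values of every list lie below 0.01. The next peak of a list was never closer than 200 bp in the combined list, 201 bp in replicate 1 and 208 bp in replicate 2. Read depth is unknown, so the lists may differ in sensitivity by an amount that cannot be calculated. The q-values were therefore used only to rank and filter peaks within 1 list.

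Overlap between lists was counted as at least 1 bp. The observed share was set against 10000 circular shifts of the first list, each moving all peaks of a chromosome by 1 random distance; shifts by a short distance keep part of the true overlap and raise the highest simulated values. Rank agreement was measured over overlapping peaks, with 100000 permutations. A planned permutation test of median q between combined peaks found in both replicates and in neither was run but is not used, because these classes were made by whether the peaks were called. Where several peaks of replicate 1 overlapped 1 peak of replicate 2, the one with the lowest q was used. Shares carry Wilson 95% intervals, which cover counting error only. The number of peaks on each chromosome was tested with a two-sided exact binomial test against the chromosome's share of length, with Benjamini-Hochberg adjustment over 6 chromosomes. Lengths were the highest peak end on each chromosome in any list, since no genome of this build was used here. The central region of a chromosome was taken as 25% to 75% of that length, by peak midpoint. Peaks are not independent replicates, and all tests over peaks describe these 2 libraries rather than the spread between worm populations.

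The peaks named below were chosen by a rule fixed before the data were examined: the 10 combined peaks with the lowest q, the 3 best combined peaks that overlap no replicate peak, and the 3 best peaks of each replicate that are absent from the combined list. Other peaks, given in the closing section (X regions among the 50 best, clusters and the first peak of chromosome II), were chosen after their values were seen. The rule also named genes, 16 gene lists had been fixed, and the position of peaks relative to gene 5′ ends and 2 motif tests (E2F and CHR elements) had been planned. The gene table at hand is of the WBcel235 assembly and was not joined to WS220 coordinates, and no sequence was used, so none of these was run and regions are given by position alone. Whether a peak is exonic, intronic or intergenic was therefore not analysed here. The transgene adds copies of the mex-5 promoter, lin-35 and unc-119 to the genome, and their reads would map to the native loci; which peaks those are was not analysed here.

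Alternatives were a 50% reciprocal overlap, midpoints within 100 bp, uniform random placement, the better 50% of each list by q, each replicate list alone and combined peaks found in both replicates. Added after seeing the data were the best 10% and the weaker 50% of the combined list, peaks of at least 100 bp, the X test without chromosome I, the tests of chromosome I, and replicate 1 reduced to the length of replicate 2. The overlap count was checked against bedtools 2.31.1 and gave the same numbers. The procedures were tested on simulated data. For the replicate overlap, 3% of 100 unrelated simulated lists of 558 peaks reached p of 0.05 or less, and a list with 50% planted overlap was measured at 50.9%. For the X test, numbers of X peaks among 5374 were drawn from a binomial distribution. With the X share set to 0.5 of its value, 100% of 200 draws were called, and with the share unaltered 5% were. Such draws treat peaks as independent, so they do not show that the test holds for peaks that lie in groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.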

Results

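The binding of germline-expressed LIN-35 in young adult hermaphrodites was recorded as 3 lists of peaks. LIN-35 is the only member of the Rb family in the worm and acts with E2F and the DREAM complex, which repress transcription. Replicate 1 held 3804 peaks covering 765 kb, replicate 2 held 558 peaks covering 204 kb, and the combined list held 5374 peaks covering 1084 kb. The median peak was 165 bp wide in replicate 1, 298 bp in replicate 2 and 153 bp in the combined list. The lowest q was 3.58e-112 in replicate 1, 1.05e-39 in replicate 2 and 3.36e-118 in the combined list. A q under 1e-05 was reached by 540 peaks of replicate 1, 102 of replicate 2 and 985 of the combined list. Many calls were narrow: 35.9% of combined peaks and 29.9% of replicate 1 peaks spanned less than 100 bp, against 0.179% of replicate 2 peaks, which was 1 peak.

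The strongest peaks lay on all 6 chromosomes. Whether any of them is a native locus of a sequence carried by the transgene was not analysed here. The combined peak with the lowest q lay on chromosome II at 8418688 to 8421614 and was 2927 bp wide (q = 3.36e-118). It ranked 1st in replicate 1, whereas in replicate 2 the same region held 2 peaks, the better of which ranked 420 with q = 0.00369. The next 4 regions had nearly equal ranks in both replicates. On chromosome III at 3866456 to 3867801 the combined q was 1.60e-112, and the overlapping peaks ranked 2 in replicate 1 and 1 in replicate 2. The region on chromosome III at 10758850 to 10759440 ranked 3 in both replicates, that on chromosome III at 7854236 to 7854891 ranked 4 in both, and that on chromosome II at 10563278 to 10563826 ranked 5 in both. The region on chromosome V at 10897001 to 10897604 ranked 7 in all 3 lists.

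The remaining 4 of the 10 best combined regions had less even support. On chromosome I at 9879314 to 9883710 a region of 4397 bp, the widest in the list, had a combined q of 7.72e-67 and rank 8 in replicate 1, but the nearest replicate 2 peak was 90454 bp away. On chromosome IV at 17279833 to 17281872 the region ranked 23 in replicate 1 and 2 in replicate 2. On chromosome III at 13462809 to 13465246 it ranked 37 in replicate 1 and 18 in replicate 2. On the X chromosome at 14525364 to 14526344 it ranked 6 in replicate 1 and 26 in replicate 2. All 10 regions were thus present in replicate 1 and 9 in replicate 2. With 1 library per list, these differences between replicates have no test of their own.

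The first comparison asked whether both replicates marked the same regions. Most of the short replicate 2 list was contained in replicate 1: 462 of its 558 peaks, or 82.8% (95% interval 79.4 to 85.7), overlapped a replicate 1 peak. Circular shifts gave 2.38% on average and 13.98% at most (one-sided permutation p = 1e-04, the smallest that 10000 shifts can give). In the other direction, 463 of 3804 replicate 1 peaks, or 12.2% (11.2 to 13.2), overlapped replicate 2, against 0.350% in shifted lists. Against only the 558 best replicate 1 peaks, the overlap of replicate 2 was 54.1% (50.0 to 58.2).

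The peaks shared by both replicates were mainly the strong ones. In the best 10% of replicate 1 by q, 64.04% (59.1 to 68.7) of 381 peaks were found in replicate 2. This share was 25.8% in the second 10% and 14.2% in the third, and in each 10% of the weaker 50% of the list it lay between 1.05% and 1.84%. Of the 50 best replicate 1 peaks, 2 were missing from replicate 2, of the 100 best, 7 were missing, and of the 558 best, 257 were. Over the 462 overlapping pairs, ranks in the 2 lists were correlated, with Spearman's rho = 0.54 and Pearson's r of the list ranks = 0.41 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). This correlation is across peaks, which are not independent replicates.

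**Figure D1:**
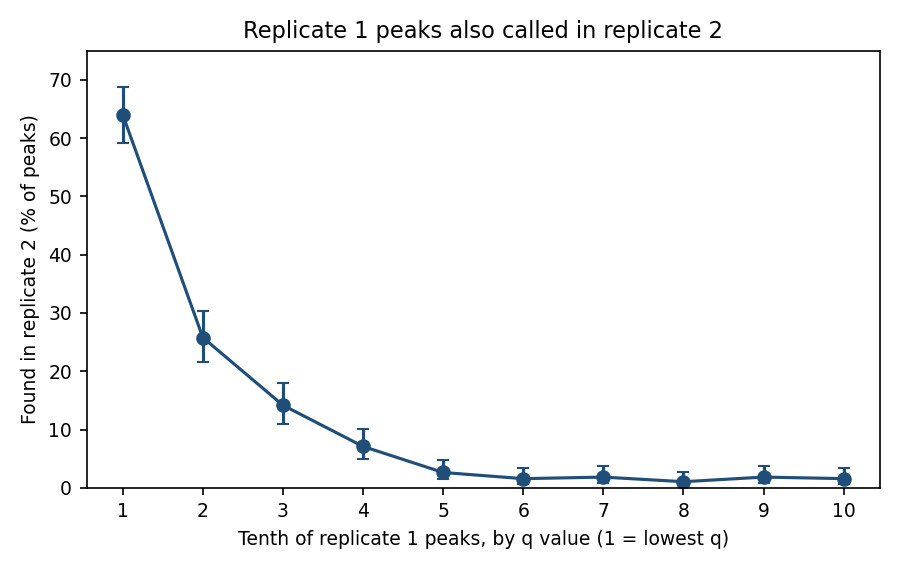
Percentage of replicate 1 peaks that overlap a replicate 2 peak (y axis) in each 10% of the replicate 1 list, ordered from the lowest to the highest q (x axis); points are shares and bars Wilson 95% intervals. The share falls from 64.04% in the first 10% to 1.58% in the last.

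The combined list was then compared with the lists of the single replicates. Of its 5374 peaks, 465 or 8.65% (7.93 to 9.43) overlapped peaks of both replicates and 2593 or 48.3% overlapped replicate 1 only. Replicate 2 alone accounted for 77 peaks or 1.43%, and 2239 peaks or 41.7% (40.4 to 43.0) overlapped no peak of either replicate. Peaks found in both replicates were the strongest and widest, with a median q of 5.29e-12 and a median width of 458 bp. Those in neither had a median q of 0.00468 and a median width of 83 bp. The medians of −log10 q were 11.3 and 2.33. The share found in both depended on which peaks were counted: it was 17.3% in the better 50% of the combined list.

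The best combined peak without support in either replicate ranked 767 and lay on chromosome III at 4216343 to 4216739 (q = 1.26e-06). The next were on chromosome II at 11651023 to 11651477 (q = 3.40e-06) and on chromosome V at 185697 to 186020 (q = 4.89e-06). Conversely, the combined list contained 81.2% (79.96 to 82.44) of replicate 1 peaks and 98.6% (97.2 to 99.3) of replicate 2 peaks. The 714 replicate 1 peaks outside it were narrow, with a median of 57 bp. The strongest of them lay near the right end of chromosome I, where the ribosomal DNA repeats of the worm are found, at 15060635 to 15060831. It ranked 178 in replicate 1 with q = 8.19e-11 and overlapped a replicate 2 peak of 22 bp at 15060793 to 15060814 with q = 0.000420, while the nearest peak in the combined list as analysed here was 108777 bp away. Why the combined list used here holds no peak at this position is not known. The next replicate 1 peaks outside the combined list were far weaker, on the X chromosome at 8422673 to 8423065 (q = 0.000288) and on chromosome II at 223935 to 224104 (q = 0.000311). Besides the peak at the end of chromosome I, the best replicate 2 peaks outside it were on chromosome IV at 14071673 to 14072149 (q = 0.00246) and on chromosome III at 3179821 to 3180092 (q = 0.00515).

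The next comparison asked how LIN-35 peaks were divided among the chromosomes, in particular on the X chromosome, most of which is transcriptionally silent in the germline. Chromosomes II and III were rich in peaks, and chromosomes I and X were poor. Chromosome III carried 19.3% (18.3 to 20.4) of combined peaks, 1.40 times its share of length, at 75.3 peaks per Mb. Chromosome II carried 18.6%, or 1.22 times its share. The X chromosome carried 732 peaks or 13.6% (12.7 to 14.6), 0.774 of its share of length of 17.6% (adjusted p = 5.96e-15, exact binomial test). Chromosome I carried 581 peaks or 10.8% (10.0 to 11.7), 0.718 of its share of 15.1% (adjusted p = 3.93e-19, exact binomial test). Chromosome IV lay slightly above its share at 1.08 and chromosome V slightly below at 0.899. These ratios refer to length alone. The number of genes on each chromosome was not used, so an excess or deficit relative to genes is not shown.

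Both replicates ordered the chromosomes in a similar way. Chromosome III had 1.55 times its share of length in replicate 1 and 1.69 times in replicate 2, and chromosome I had 0.548 and 0.595. The X chromosome carried 13.3% (12.2 to 14.4) of replicate 1 peaks and 7.35% (5.46 to 9.82) of replicate 2 peaks. When replicate 1 was reduced to its 558 best peaks, its X share was 6.63% (4.85 to 9.01). For X and for chromosome I the exact binomial test in each replicate list gave adjusted p of 4.86e-05 or less. For chromosome V the deficit was not past the threshold in replicate 2 (adjusted p = 0.466, exact binomial test).

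**Figure D2:**
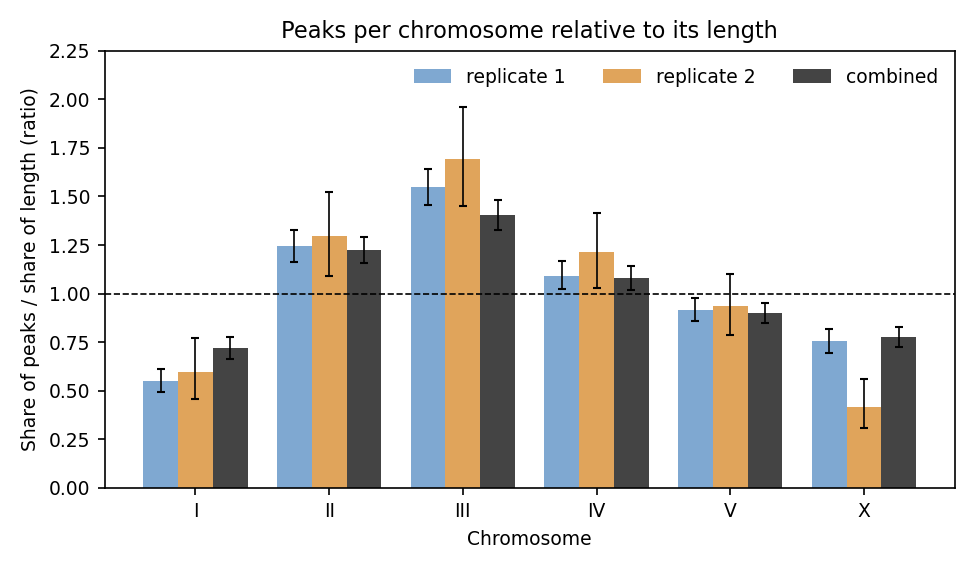
Share of peaks on each chromosome divided by its share of summed length (y axis, ratio) for the 6 chromosomes (x axis) in the replicate 1, replicate 2 and combined lists; error bars are Wilson 95% intervals and the dashed line marks a share equal to that of length. Chromosome III lies highest, at 1.40 in the combined list, and chromosomes I and X lie below 1 in every list.

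The X deficit of the combined list lay in its stronger peaks, though none was detected among the 50 or the 100 best. With cuts chosen after the data were seen, X held 11 of the 50 best combined peaks or 22% (12.8 to 35.2), and 16% (10.1 to 24.4) of the 100 best, neither distinguishable from the share of length (p = 0.456 and 0.793, exact binomial test). In replicate 2, by contrast, X held 2 of the 50 best peaks or 4% (1.10 to 13.5) and 0 of the 20 best. Both lay below the share of length (p = 0.00818 and 0.0364, exact binomial test, unadjusted). X peaks had a median rank of 3388 in the combined list against 2567 for autosomal peaks, and their mean rank was 559 places lower in the order (two-sided permutation test, adjusted p = 3e-05 over 6 chromosomes). In the 25% of combined peaks with the lowest q, 7.14% (5.88 to 8.65) lay on X. The share was 12.7% in the second 25%, 15.8% in the third and 18.8% (16.84 to 21.02) in the last. Replicate 1 had the same order, from 7.78% to 17.6%. Replicate 2 did not: its successive shares were 9.29%, 7.91%, 3.57% and 8.63%, the last (5.01 to 14.5) still below the share of length. In the weaker 50% of the combined list as a whole the X share was 17.3% (15.9 to 18.8), which was not distinguishable from the share of length (p = 0.704, exact binomial test). Among the 465 peaks found in both replicates, 33 or 7.10% (5.098 to 9.799) lay on X. Chromosome III peaks, in contrast, had a median rank of 2244 against 2790 for other chromosomes (adjusted p = 3e-05, permutation test).

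**Figure D3:**
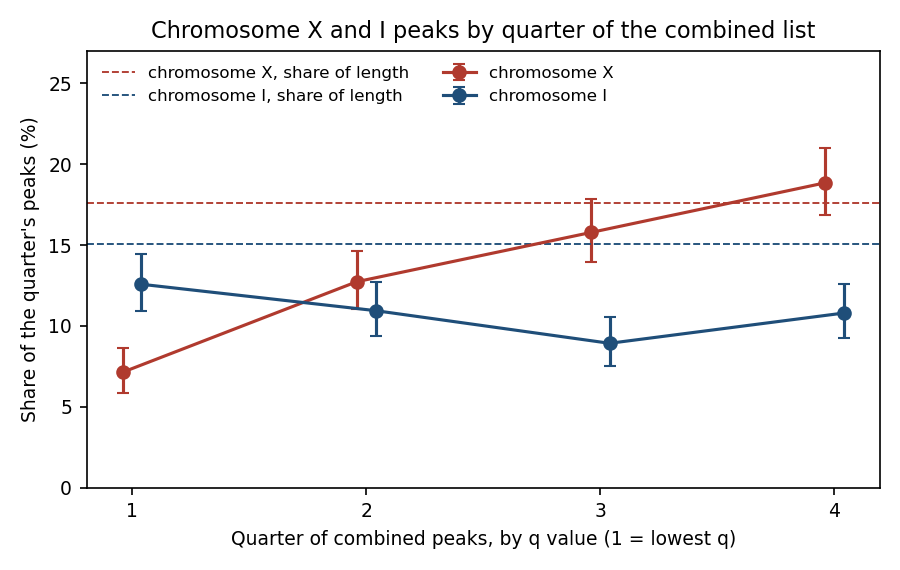
Percentage of peaks on chromosome X and on chromosome I (y axis) in each successive 25% of the combined list, from the lowest to the highest q (x axis); bars are Wilson 95% intervals and dashed lines show each chromosome's share of length. The X share rises from 7.14% to 18.8%, while chromosome I stays below its share of length in all 4 parts.

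The last comparison concerned position along the chromosome. The central part of worm autosomes holds most conserved and broadly expressed genes, and the arms are richer in repeats. Of 4642 autosomal combined peaks, 56.6% (55.2 to 58.1) lay in the central 50% of their chromosome, above the 50% of length (p = 1.57e-19, exact binomial test). The share was 55.0% in replicate 1 and 59.2% in replicate 2. In the best 10% of combined peaks it was 53.4% (49.0 to 57.7), which did not pass the threshold. Among single autosomes, the central share of combined peaks was 61.7% on V, 57.5% on II and 57.3% on III, each past the threshold (adjusted p of 5.34e-06 or less, exact binomial test). It was 53.0% on IV and 51.5% on I, neither of which passed. In replicate 2 alone, chromosome II did not pass (53.6%, adjusted p = 0.606, exact binomial test) and chromosome IV did (61.0%, adjusted p = 0.0419). On the X chromosome 49.3% (45.7 to 52.9) of peaks lay in the central 50%. These values refer to length alone; gene density was not used.

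**Figure D4:**
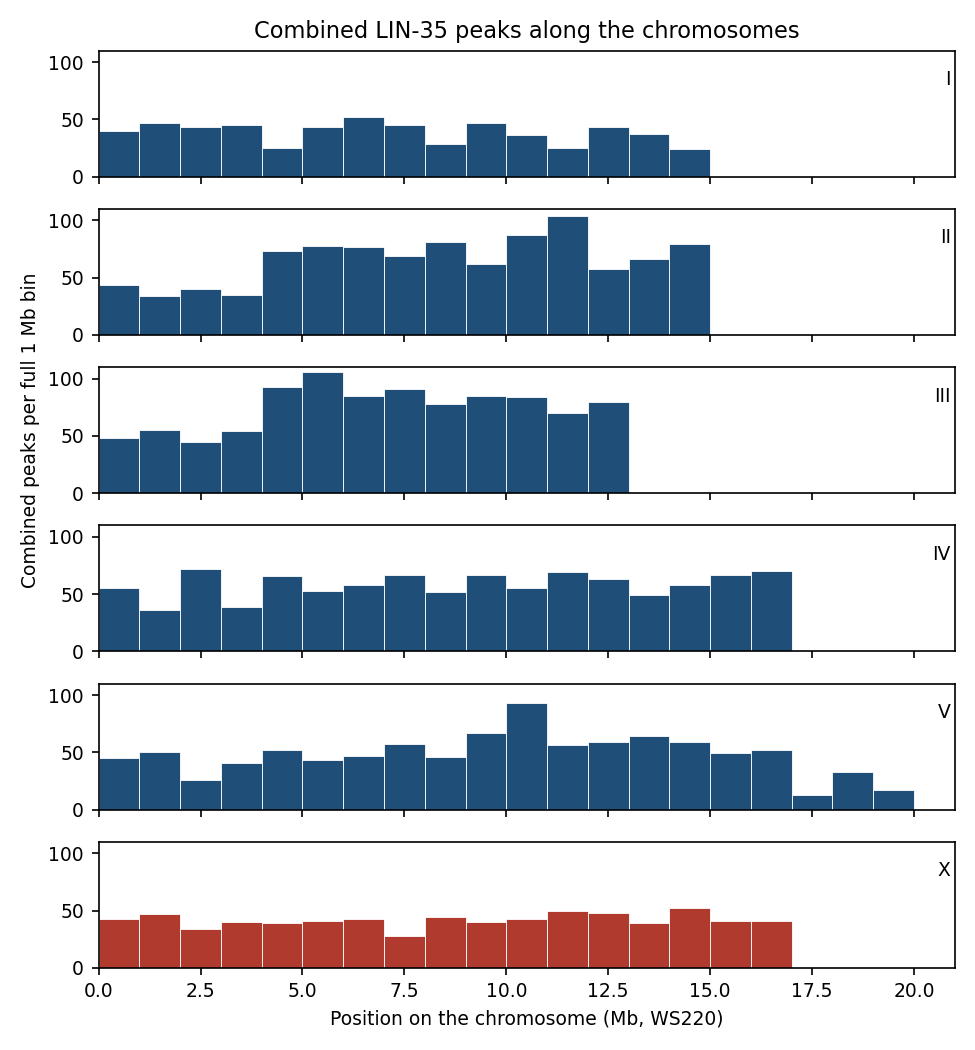
Number of combined peaks in each full 1 Mb bin (y axis) along the 6 chromosomes (x axis, Mb on WS220). Chromosome I bins hold 24 to 52 peaks and X bins 28 to 52, while bins of chromosome III hold 45 to 106.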

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

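The overlap of the replicates, their rank agreement and the excess in autosome centres kept their direction under every alternative listed above. So did the deficits of chromosomes X and I. In other cuts the X share was not always below its 17.6% of length. It was 22% among the 50 best combined peaks and 26% among the 50 best replicate 1 peaks. Among the 1343 combined peaks with the highest q it was 18.8%. The intervals of these shares included 17.6%. Among the 50 best replicate 2 peaks the X share was 4%. The overlap of replicate 2 with replicate 1 ranged from 54.1% to 90.3%, and each value was above its shifted or random lists. The rank correlation was 0.64 with a reciprocal overlap. Of these, 3 calls were lost, in settings added after seeing the data: the X share in the weaker 50% of the combined list (17.3%), and the chromosome I share (12.6%) and the central share (53.4%) in its best 10%, which holds 538 peaks. The share of combined peaks found in both replicates moved to 6.29% with a reciprocal overlap, 17.3% in the better 50% of the list and 13.5% among peaks of at least 100 bp, the last added after seeing the data. With replicate 1 alone or replicate 2 alone, the calls on X, on chromosome I and on autosome centres as a whole were kept. Among the results for single chromosomes and for the best peaks, replicate 2 alone lost the deficit of chromosome V (adjusted p = 0.466, exact binomial test), the central excess of chromosome II (adjusted p = 0.606) and the contrast among the best X peaks (adjusted p = 0.561, Fisher's exact test), and gained a central excess on chromosome IV (adjusted p = 0.0419). Replicate 2 holds only 558 peaks, so the losses on chromosomes V and II need not mean different shares. The ratio of chromosome V to its share of length was 0.935 in replicate 2 and 0.899 in the combined list. The interval of the central share of chromosome II in replicate 2 (44.4 to 62.7) included the 57.5% of the combined list. No paired analysis was possible because no processed input files were analysed, so the groups that share replicate numbers could not be compared. Tests of gene 5′ ends, gene lists and motifs were not run, since no annotation or sequence of the WS220 build was used. Expectations from gene numbers per chromosome were not calculated either. Ranking by a second significance value was not run, since each peak has a q-value alone. Read depth is unknown, so a region missing from replicate 2 was not detected there and is not shown to be unbound.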

Other observations

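The patterns in the paragraphs on X regions, chromosome arms and clusters were noticed in the data and tested on the same data. Of the tests of explanations, those on the number of peaks in replicate 2 and on a missing stretch of chromosome I were chosen after the result was seen.

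The X share of combined peaks was higher among the 50 best than among those that followed them. Of the 50 best combined peaks, 11 or 22% (12.8 to 35.2) lay on X, while of those ranked 51 to 500, 21 of 450 or 4.67% (3.07 to 7.03) did (two-sided Fisher's exact test, p = 0.000131 adjusted over the 3 lists). The 50 best did not differ past the threshold from the whole rest of the list (p = 0.0951, Fisher's exact test) or from the X share of length (p = 0.456, exact binomial test), and 1 of the 10 best lay on X. Replicate 1 showed the same contrast, with 13 of 50 against 21 of 450 (adjusted p = 1.24e-05, Fisher's exact test). This is not separate support, since 8 of the 10 best combined peaks were also among the 10 best of replicate 1 (6 for replicate 2). Replicate 2 did not show the contrast, with 2 of 50 against 33 of 450 (adjusted p = 0.561, Fisher's exact test), and 0 of its 20 best peaks lay on X. The adjustment over 3 lists does not cover the choice of these cuts after the data were seen. All 11 regions overlapped peaks in both replicates, with a median rank of 17 in replicate 1 and 68 in replicate 2. They were spread along the chromosome, the best at 14525364 to 14526344, 16929506 to 16931980, 11093775 to 11094409, 6296093 to 6296850, 2996481 to 2997398 and 8036072 to 8036925. Which annotated features they overlap was not analysed here, and the difference between the replicates in this contrast was not tested. Over the best 10% of combined peaks, the X share was 7.06%.

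The arms differed on chromosomes II, III and V of the combined list. On chromosome II the right 25% held 286 combined peaks and the left 25% held 139, and on chromosome III the right held 277 and the left 166 (adjusted p = 5.08e-12 and 4.50e-07, exact binomial test over 6 chromosomes). Both replicates showed this, with 215 against 95 and 41 against 10 peaks on chromosome II, and 214 against 152 and 33 against 16 on chromosome III. On chromosome V the left 25% was the richer, with 221 against 166 combined peaks (adjusted p = 0.0120, exact binomial test), 177 against 125 in replicate 1 and 27 against 8 in replicate 2. The left and right 25% did not differ past the threshold in the combined list on chromosome I (159 and 123 peaks, adjusted p = 0.0554), chromosome IV (223 and 253, adjusted p = 0.220) or X (184 and 187, adjusted p = 0.917, exact binomial test for each). In replicate 1 alone chromosome I did (94 and 62, adjusted p = 0.0192, exact binomial test).

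Peaks also gathered in clusters. Combined peaks no more than 2000 bp apart formed 285 clusters of at least 3 peaks, against 66.4 on average and 100 at most in 1000 random placements within chromosomes (one-sided permutation p = 0.001, the smallest that these can give). Random placement takes no account of where genes lie, and broad regions split into several calls would also form clusters. The count therefore does not show grouping of separate binding sites. The largest held 11 peaks over 10464 bp on chromosome II at 10541921 to 10552384, with 8 peaks in replicate 1 and 1 in replicate 2. A cluster of 9 peaks lay on chromosome III at 1616203 to 1626232, with 7 peaks in replicate 1 and 3 in replicate 2. The first peak of chromosome II lay against its left end in all 3 lists, starting at 133 in replicate 1 and the combined list and at 135 in replicate 2.

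Replicate 2 had far fewer peaks than replicate 1. Binding at a wholly different set of regions is argued against by the overlap of 82.8% (79.4 to 85.7) of its peaks with replicate 1, and by 54.1% (50.0 to 58.2) with the 558 best replicate 1 peaks alone, against 0.563% in shifted lists. A difference at part of the regions stays open, since 257 of those 558 peaks, or 46.1%, were missing from replicate 2. Lower sensitivity of replicate 2 remains as a candidate explanation: a replicate 1 peak found in replicate 2 had a lower q than one not found with a probability of 0.889. This value does not single it out, since weak replicate 1 calls that mark no binding would give the same. Whether any loss of sensitivity came from read depth, the precipitation or the control is open, since depth is unknown. The region of 4397 bp on chromosome I ranked 8 in replicate 1 but was absent from replicate 2. The best region on chromosome II ranked 1 in replicate 1 but 420 in replicate 2. The chromosome I region stands apart from the trend for low-q peaks to be found. The chromosome II region was found in replicate 2 and stands apart from the agreement in rank alone. Whether either is a locus copied in the transgene, where a peak need not mark binding at the native site, was not analysed here.

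Combined peaks in neither replicate may be weak binding that only the combined data could call, or calls placed by chance. Placement of all of them by chance, evenly over length, is argued against by their X share of 15.4% (13.9 to 16.9), below the 17.6% of length. It is also argued against by the 16.8% of them within 1000 bp of a replicate peak, compared with at most 10.6% in 1000 circular shifts, and by their central share of 57.3% (55.0 to 59.5) on autosomes. These values do not bear on calls from a background that is itself uneven along the genome, which was not tested. A part of these peaks being chance calls stays open: the X share of the last 25% of the combined list was 18.8%, not below that of length. Being near a replicate peak also fits broad regions that were split into several calls, so it does not show separate binding sites.

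The low peak density of chromosome I has no counterpart in the design, which compares no groups, and no biological explanation was tested. A missing stretch of chromosome I is argued against by its bins: 0 of 15 full 1 Mb bins held more combined peaks than the median bin of chromosomes II to V (58). A shift of the calling threshold on chromosome I cannot be told apart from a true lack of sites. In the best 10% of combined peaks the share was 12.6% (10.1 to 15.7), an interval that includes the 15.1% of length. The intervals of other sets of strong peaks lay below 15.1%. These were the best 25% of combined peaks at 12.6% (10.9 to 14.5), the 558 best replicate 1 peaks at 11.1% (8.76 to 13.99) and the peaks in both replicates at 10.5% (8.06 to 13.66). The best 10% and the best 25% had nearly the same share, and the interval of the best 10% was wider because it holds fewer peaks. The other sets argue against a deficit in the weaker peaks alone, while a shift acting on strong and weak chromosome I peaks alike was not tested. Chromosome I peaks ranked better, with a mean rank difference of -162 (chromosome I minus the others) (adjusted p = 0.0200, permutation test), and their share was 8.25% in replicate 1 against 10.8% in the combined list.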
